A study of Arabidopsis thaliana with 12 samples.

How the data were processed

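The submitters' processing notes name the TAIR10 build and the tools Bowtie 1.0.0, BWA 0.7.17-1188, Trimmomatic 0.36, TopHat2 2.0.9 and Cuffdiff, without roles. The deposited GRID-seq files list pairs of short mapped ends with the read numbers behind each pair, and hold no normalized value. The deposited Hi-C files list pairs of anchors called per library, with the count of read pairs between them as the authors gave it. The first end was taken as RNA because its strand was biased within genes: the median share of the majority strand over protein-coding genes with at least 30 ends was 81.3% at the first end and 53.8% at the second in wild type replicate 1. In the leaf libraries of replicate 2 the first end gave 67.1% and 66.7%.

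Ends were assigned to genes with a gene table of assembly TAIR10.1, which is not the build named in the notes. None of its coordinates are given, and its fit to the nuclear ends was checked by shifting them: 74.9% of first ends of wild type replicate 1 lay in protein-coding genes as placed, against 59.0% and 58.3% after shifts of 5 kb. The table gives no gene strands or exons, so ends were counted on both strands, antisense genes cannot be told apart from their partners, and exon and intron shares were not analysed here. An RNA end was counted where both ends were nuclear and the midpoint lay in a single gene; in wild type replicate 1, 85.9% of nuclear pairs met this, 4.55% lay in overlapping genes and 9.51% outside genes. DNA ends were counted in the gene body and 1 kb on each side, from pairs with the RNA end over 10 kb away or on another chromosome. Pericentromeric windows were 500 kb windows with under 35% of bases in protein-coding genes.

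The counts were tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood fit over all 10 GRID-seq libraries with group means, two-sided, Benjamini-Hochberg adjusted p under 0.05). Standard errors are the log2 fold change divided by the square root of the F statistic. DESeq2 1.42.0 was an alternative. The 13 gene lists of 201 genes were fixed before the data were examined and tested with fry and camera of limma 3.58.1 (preset correlation 0.01, and estimated). R 4.3.3, Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used. Named genes followed a rule fixed with the lists: adjusted p under 0.05, a log2 fold change of at least 1 in size, an average log2 CPM of at least 3 and no overlap between treated and mock libraries, then the 10 largest rises and falls for RNA ends and 5 for DNA ends, the 5 members with the smallest p of each list that fits the treatment, and the 10 genes with most RNA ends in the wild type. Genes in no part of the rule that are named were chosen after their values were seen.

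Tested on simulated data with 200 changed genes, the RNA test of heat recovered 10.4% of 2-fold, 67.2% of 4-fold and 92.4% of 8-fold changes among 23685 genes, with 4 false calls, and that of DC3000 4.48%, 73.1% and 98.5% among 23779. The DNA test of heat recovered 56.7%, 95.5% and 100% among 36005, with 11 false calls, and that of DC3000 67.2%, 100% and 100% among 35999, with 12. Simulated libraries shared a common mean for each gene apart from the changed genes, and genes varied independently. The leaf replicates differed across whole gene lists, which the simulation does not include. Its recovery for DC3000 therefore does not show which changes the lack of calls there excludes.

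Several pairs can share a read number: 19.9% of read numbers in wild type replicate 1 and 30.4% in replicate 2 stood in more than 1 pair, with the RNA end in common. Deposited pairs were taken as they stand. This choice was made after several ways of counting had been tried on the files; counting only reads with a single second end, 1 pair per read number, or each read number, leaving out pairs under 200 bases apart, and taking any second end were therefore added as alternatives after seeing the data. The background from organelle RNA, the redrawn chance level and the division by bin totals were also added then. No 2 deposited GRID-seq pairs had the same coordinates and strands, so the planned counting of identical pairs once changes nothing there. Replicate numbers are shared by the groups, but the labels do not say that a number marks a shared batch.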

Results

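RNA contacts with chromatin were measured by GRID-seq in Arabidopsis thaliana. GRID-seq joins RNA to nearby DNA in fixed nuclei through a linker, so that each read pair gives the position of an RNA end and of a DNA end. The 10 GRID-seq libraries fell into 5 groups of 2: untreated 12 day old seedlings (called wild type), seedlings of the same age held for 0.5 h at 22 °C (mock) or at 37 °C (heat), and leaves of 24 day old plants 24 h after a 10 mM MgSO4 mock treatment or after Pseudomonas syringae DC3000 at an OD600 of 0.001. A further 2 libraries were BL-Hi-C, a chromosome conformation assay, of untreated seedlings. The GRID-seq libraries held 4237622 and 5127873 pairs in the wild type, 2130372 and 2150921 in the mock seedlings, 1458208 and 3422666 after heat, 2241089 and 8741491 in the mock leaves, and 1696898 and 6823867 in the leaves given DC3000, as replicates 1 and 2. The Hi-C libraries held 2417371 and 9691137 read pairs between anchors of the same chromosome. The labels do not say that replicates came from separate cultures or plants, so p-values measure the spread between these libraries, which may be technical.

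The wild type libraries describe which RNAs were joined to nuclear DNA without treatment. RNA ends came mainly from protein-coding genes, which took 76.2% ± 1.72 of nuclear pairs (SD, n = 2). Long and other noncoding RNA genes took 5.07% ± 0.871, small nuclear and small nucleolar RNA genes 2.24% ± 0.324, annotated ribosomal RNA genes 1.52% ± 0.283, and transfer RNA genes 0.0863% ± 0.0197. The gene with most RNA ends was AT3G06365, annotated as a miscellaneous RNA, with 3.52% ± 0.930 of nuclear pairs. It was followed by the ribosomal RNA gene AT3G41768 with 1.51% ± 0.282 and by U2.4 (AT3G56825), a U2 spliceosomal RNA gene, with 0.612% ± 0.226. The next were the pseudogene AT1G79245 (0.373%), the long noncoding RNA AT3G06355 (0.243%), U2.7 (AT5G61455, 0.240%), U2.6 (AT3G56705, 0.205%) and the miscellaneous RNA AT1G09915 (0.168%). AT3G06365 and AT3G06355 are neighbours of AT3G41768, and both are counted in the 5.07% of long and other noncoding RNA genes. A 20 kb window of chromosome 3 around these genes, set after the data were seen, held 5.37% ± 1.26 of RNA ends, against the 1.52% in genes annotated as ribosomal RNA. The U2 genes and the ribosomal RNA genes have near-identical copies, so the split of ends among copies is uncertain. The protein-coding genes among the leading 10 were AT3G54500 (0.142% ± 0.0170) and RCA (AT2G39730), the activase of the carbon-fixing enzyme Rubisco, at 0.134% ± 0.0490.

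Most pairs joined RNA to DNA of another chromosome. In the wild type, 67.5% ± 0.750 of nuclear pairs lay between chromosomes, 28.2% ± 0.373 lay over 10 kb apart on the same chromosome, and 4.31% ± 0.376 lay within 10 kb (SD, n = 2). Pairs on the same chromosome were 1.55 ± 0.0310 times as frequent as the share given by independent pairing of the chromosomes' RNA and DNA ends. That share was 20.9%, against 32.5% observed, so pairs between chromosomes were less frequent than independent pairing gives. Pairs within 10 kb were 76.2 ± 16.5 times as frequent as when DNA ends were redrawn from all DNA ends of the library. Pairs under 200 bases apart made up 1.88% ± 0.0232 of nuclear pairs, and without them the near share was 2.23% in replicate 1 and 2.74% in replicate 2, and the ratio 36.5 and 52.9. With reads that had a single second end the ratio was 97.1 and 139. After heat the near share was 6.47% ± 3.03, against 6.39% ± 0.0364 in its mock (exact permutation test, two-sided, p = 1). The heat libraries stood apart at 8.61% and 4.33%, so the difference was -2.06 points without replicate 1 and 2.22 without replicate 2. In leaves the near share was 3.90% ± 2.52 in the libraries labelled DC3000 and 4.35% ± 3.30 in their mock (exact permutation test, two-sided, p = 1). With 2 libraries against 2, the exact test cannot go below 0.33. The leaf libraries of replicate 1 had near shares of 6.68% and 5.68%, and the deeper libraries of replicate 2 had 2.02% and 2.11%.

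DNA ends of far pairs lay in genes more often than the genome share of genes. Gene bodies held 1.19 ± 0.000262 times their share of the genome and regions within 1 kb of a gene 0.727 ± 0.00514 times (SD, n = 2). Other intergenic sequence held 0.543 times its share in replicate 1 and 0.529 times in replicate 2. Pericentromeric windows held 0.306 ± 0.0230 times their share. DNA ends paired with chloroplast RNA, which is made outside the nucleus and serves as a background measured in the same libraries, gave 1.19 ± 0.000537 for gene bodies and 0.355 ± 0.0348 for pericentromeric windows. Those paired with mitochondrial RNA gave 0.381 ± 0.0341 for pericentromeric windows. The gene body ratio with nuclear RNA was no higher than that with chloroplast RNA.

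Heat raised RNA ends of chaperone and small heat shock protein genes. Of 24175 genes tested, 114 had more RNA ends after heat and 0 had fewer (edgeR quasi-likelihood test, adjusted p under 0.05), and 849 genes had an unadjusted p under 0.05. As in the other main fits given here, that share of genes lay below the 0.05 that uniform p-values would give. The p-values thus ran high, in a fit that takes the spread from all 10 libraries, leaves included. DESeq2 called 131 higher and 1 lower. The largest rise was in Hop3 (AT4G12400), a co-chaperone that links HSP70 and HSP90, with a log2 fold change of 6.01 (SE 0.665, adjusted p = 0.000405 by edgeR). AT5G48570, which encodes an FKBP-type peptidyl-prolyl isomerase, rose by 5.89, the disaggregase gene HSP101 (AT1G74310) by 5.87, HSP90.1 (AT5G52640) by 5.83 and the co-chaperone gene BAG6 (AT2G46240) by 5.71 on the log2 scale. HSP17.6II (AT5G12020) rose by 5.61, the heat shock transcription factor gene HSFA2 (AT2G26150) by 5.58, AT1G07400 by 5.54, AT5G51440 by 5.53 and HSP70 (AT3G12580) by 5.43. These 10 and the rest of the 114 were higher in both heat libraries than in either mock library. Over all genes tested, 36.9% did not overlap between heat and mock in either direction, against 33.3% by chance. Leaving out single libraries lowered the count to between 32 (without mock replicate 1) and 84 (without heat replicate 2), with 34 without mock replicate 2 and 48 without heat replicate 1. With the spread taken from the 4 libraries of the comparison alone, 192 genes were called higher and 32 lower (edgeR). There 1787 of 20682 genes had an unadjusted p under 0.05, so the absence of falls depends on the libraries in the fit.

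**Figure D1:**
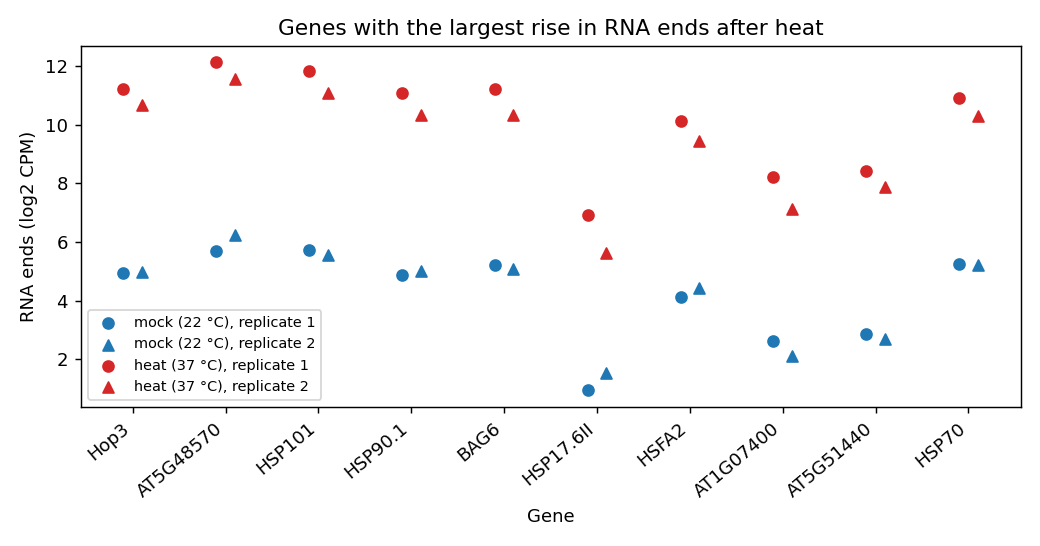
RNA ends per gene (log2 CPM, vertical axis) of the 10 genes with the largest rise after heat, with 1 point per library. The heat libraries lie above both mock libraries for every gene shown, for example at 11.2 and 10.7 against 4.95 and 4.99 for Hop3.

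Of the heat gene lists, 18 of 21 measured genes of the chaperone list rose, with 19 adjusted over the list alone, and their median log2 fold change was 4.06. The list also holds GolS1 (AT2G47180) and APX2 (AT3G09640), which encode a galactinol synthase and an ascorbate peroxidase and not chaperones, and both rose (by 3.58 and 2.62, edgeR). Fes1A (AT3G09350) rose by 4.62 and Hsp70b (AT1G16030) by 4.06. Of the small heat shock protein genes, 14 of 16 rose (15 adjusted over the list alone), with a median of 4.31. AT1G54050 rose by 5.21, AT1G53540 by 4.56 and AT2G29500 by 4.19. Small heat shock protein and HSP70 genes include close paralogs, so their single values are uncertain. Of the 15 heat regulators, 5 rose (9 adjusted over the list alone), with a median of 1.69: HSFA2, the coactivator gene MBF1C (AT3G24500, 4.03), HSFA7A (AT3G51910, 3.50), DREB2A (AT5G05410, 2.94) and HSF4 (AT4G36990, 3.03). The set test fry gave adjusted p = 0.00126 for chaperones, 0.00126 for small heat shock proteins and 0.00807 for regulators, and camera, which called the same 3 lists with a preset correlation, gave adjusted p = 0.0103, 0.0103 and 0.0341 with an estimated correlation. No member of the photosynthesis or clock lists passed the gene test in the fit over all 10 libraries (edgeR). With the 4 libraries of the comparison alone, 2 named members of these lists passed, so the lack of calls does not show a lack of response. Of the 39 photosynthesis genes 38 had negative values, with a median of -0.24 (0.03 in replicate 1 and -0.49 in replicate 2, fry adjusted p = 0.892), and RBCS1B (AT5G38430) stood at -1.08 (edgeR adjusted p = 1.00). In the clock list, PRR9 (AT2G46790) stood at 1.16 and RVE8 (AT3G09600) at -1.21 (edgeR adjusted p = 0.576 and 0.875), and fry gave adjusted p = 0.211 for movement on balance one way and 0.0142 for change in either direction, while camera gave adjusted p = 0.105 with a preset and 0.258 with an estimated correlation. The fry call for change in either direction was lost with reads that had a single second end. No gene of the salicylate defence, pattern immunity, jasmonate and coronatine, or housekeeping lists passed (edgeR), with medians of -0.08, -0.36, -0.10 and -0.15. The marker lists of root, guard, dividing, and vascular or epidermal cells had medians of 0.00, -0.11, 0.14 and 0.10 (fry adjusted p = 0.892 for each).

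As a background without heat, mock seedlings were compared with wild type seedlings. Here 0 of 24175 genes passed by edgeR, with 444 at an unadjusted p under 0.05, and DESeq2 called 0. The median log2 difference of the chaperone list was 0.29, that of the small heat shock protein list 0.11, that of the photosynthesis list 0.37 (0.09 in replicate 1 and 0.71 in replicate 2) and that of the jasmonate and coronatine list -0.61. In the last list the replicates had opposite signs, 0.36 and -1.13. With a preset correlation camera called the chaperone, photosynthesis, and jasmonate and coronatine lists (adjusted p = 0.0147, 0.0165 and 0.0165), and with an estimated correlation none of them (adjusted p = 0.813 for each).

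DNA ends of far pairs also rose at genes whose RNA ends rose with heat, and at neighbours of such genes. Of 36174 genes tested, 10 had more DNA ends after heat and 0 had fewer (edgeR quasi-likelihood test), with 655 at an unadjusted p under 0.05 and 12 called by DESeq2. AT5G48570 rose by 2.35 (SE 0.172, edgeR adjusted p = 3.28e-07), HSP90.1 by 1.66, the neighbour of AT5G48570, AT5G48575, by 1.54, HSP70 by 1.54 and HSP101 by 1.35 on the log2 scale. Hop3, SR45a (AT1G07350), AT4G09150, AT1G74300 and AT5G52650 were the others. AT5G48575, AT1G74300 and AT5G52650 adjoin AT5G48570, HSP101 and HSP90.1, and a DNA end near both neighbours was counted for each, so these calls are not separate loci. For RNA ends AT1G74300 stood at 1.67 and AT5G52650 at -0.13 (edgeR adjusted p = 0.539 and 1.00), and AT5G48575 had 15 RNA ends in the heat libraries. Between mock and wild type seedlings 0 genes passed for DNA ends by edgeR, with 1036 at an unadjusted p under 0.05. With reads that had a single second end, 0 genes passed by edgeR, with 761 at an unadjusted p under 0.05. In the heat libraries the far second ends lay on the strand of the gene's RNA ends in a median of 73.8% over the 9 called genes with at least 30 RNA ends. In the called genes whose RNA ends rose, the share ran from 65.4% in SR45a to 83.2% in AT5G48570, and in reads with a single second end from 45.3% in SR45a to 61.2% in HSP90.1. In AT1G74300 and AT5G52650, where DNA ends rose by 1.32 and 1.28 (edgeR), the share was 54.3% and 51.4%, against 42.9% and 59.2% in mock. Strand shares were taken in gene bodies alone. Fold changes also count 1 kb on each side, which can hold ends of the adjoining gene. Counted in gene bodies without flanks, 12 genes passed by edgeR, with 7 of the 10 among them. The RNA strand of AT5G48575 was not defined, with 53.3% of its RNA ends on the majority strand. Leaving out single libraries left 1 (without mock replicate 1), 2 (without mock replicate 2), 2 (without heat replicate 1) or 3 genes (without heat replicate 2).

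**Figure D2:**
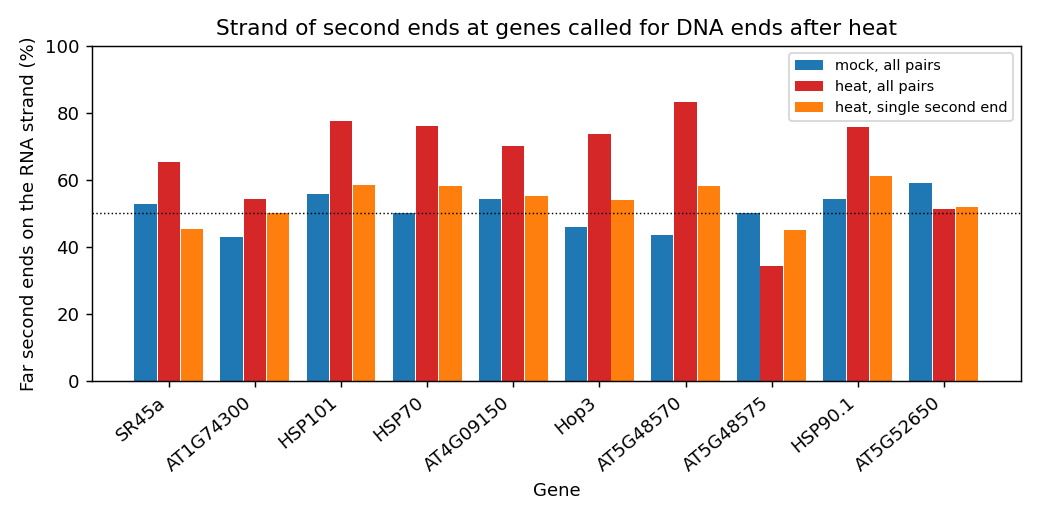
Percent of far second ends on the strand of the gene's RNA ends (vertical axis, from 0) for the 10 genes called for DNA ends after heat, in pooled mock libraries, pooled heat libraries and heat reads with a single second end; the dotted line marks 50%. In AT5G48570 the share was 43.7% in mock, 83.2% in heat and 58.2% in heat reads with a single second end; AT5G48575 has too few RNA ends to define a strand.

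In leaves, the libraries labelled DC3000 were compared with their mock. Set against the mock of the same number, the replicates differed in opposite directions. The labels do not say that same-numbered libraries are pairs, and the differences by replicate given here depend on that matching. The spread within each group was large: the jasmonate and coronatine list had means of 8.29 and 5.73 log2 CPM in mock. In DC3000 its means were 6.13 and 7.52. In the jasmonate and coronatine list, which holds genes induced by the hormone jasmonate and by the bacterial toxin that mimics it, the median log2 difference was -2.14 in replicate 1 and 2.01 in replicate 2. In the photosynthesis list it was 1.65 in replicate 1 and -1.53 in replicate 2, and in the salicylate defence list -0.87 and 0.49. Of 24175 genes, 0 differed in RNA ends by edgeR, with 104 at an unadjusted p under 0.05, and DESeq2 called 0. For DNA ends, 0 of 36174 genes passed by edgeR, with 355 at an unadjusted p under 0.05, and DESeq2 called 0. Across 19023 genes, which are not independent, the log2 differences of the 2 replicates had a Pearson r of -0.65, against 0.35 for heat. In fry, the adjusted p of each of these 3 lists, and of every other list, was 0.923. All 39 photosynthesis genes had positive values in the fit, with a median of 0.87, although replicate 2 went the other way. The heat chaperone, small heat shock protein and heat regulator lists had medians of -0.15, 0.05 and -0.07, and the pattern immunity, clock and housekeeping lists -0.01, -0.04 and 0.06. The replicates again differed in direction in some of these: the pattern immunity list stood at 0.68 in replicate 1 and -0.89 in replicate 2, the heat chaperone list at -0.94 and 0.61, and the small heat shock protein list at -0.73 and 0.05. Markers of root, guard and dividing cells had medians of -0.14, 0.13 and 0.12. Markers of vascular or epidermal cells had a median of 0.26, with 0.80 in replicate 1 and -0.42 in replicate 2, the directions of the photosynthesis list. Replicate 1 and replicate 2 also differed in the share of DNA ends on the chloroplast genome, at 11.5% and 0.862% in mock and 10.4% and 1.32% in DC3000. CORI3 (AT4G23600) stood at 9.16 log2 CPM in the library labelled mock replicate 1, 4.67 in mock replicate 2, 6.69 in DC3000 replicate 1 and 7.44 in DC3000 replicate 2. VSP1 (AT5G24780) stood at 6.04, 1.59, -0.48 and 4.07 in the same order, and CAB3 (AT1G29910), a chlorophyll-binding protein gene, at 6.43, 5.21, 8.93 and 3.46. CAB3 has near-identical copies, so its own level is uncertain. The VSP1 value of -0.48 in DC3000 replicate 1 is the floor given to a gene without RNA ends, and not a measured level. No gene of the lists passed, and 15.0% of all genes did not overlap between groups, against 33.3% by chance. WRKY38 (AT5G22570), the member of the salicylate list with the smallest p, stood at -0.97 (SE 0.338, edgeR adjusted p = 1.00). In the pattern immunity list CYP71A13 (AT2G30770) had the smallest p, at 0.78 (edgeR adjusted p = 1.00), and in the clock list AT5G64170, at 0.59 (edgeR adjusted p = 1.00). Without DC3000 replicate 2, 3 genes passed for RNA ends and 22 for DNA ends, and without DC3000 replicate 1, 0 and 3.

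**Figure D3:**
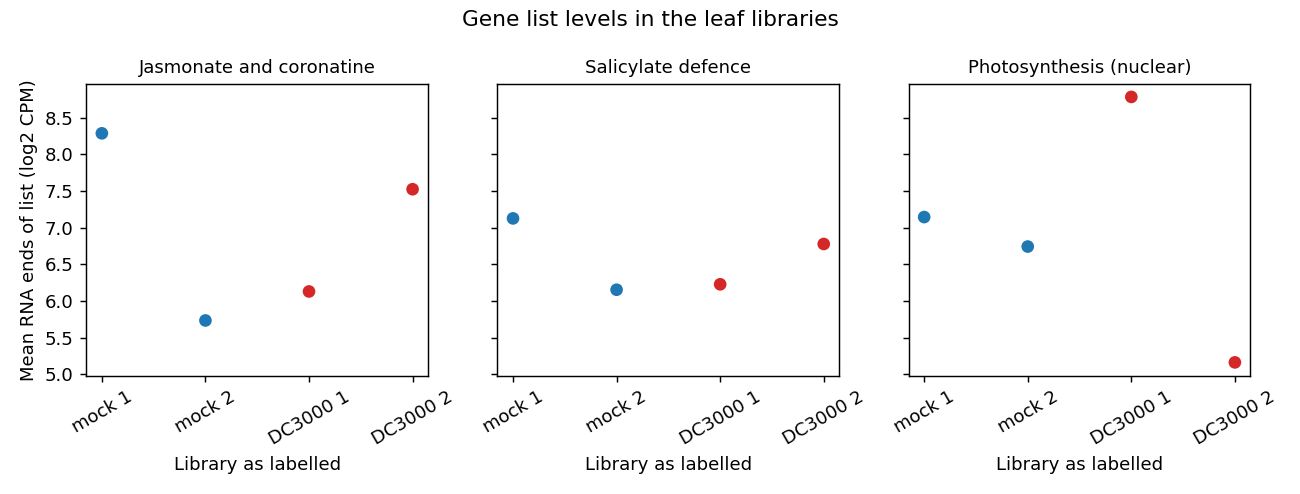
Mean RNA ends of 3 gene lists (log2 CPM, vertical axis) in the 4 leaf libraries as labelled, with 1 point per library. Mock replicate 1 and DC3000 replicate 2 had the higher jasmonate and coronatine levels, 8.29 and 7.52, against 5.73 in mock replicate 2 and 6.13 in DC3000 replicate 1.

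GRID-seq and Hi-C of untreated seedlings were compared to see how contacts of RNA with DNA lie against contacts of DNA with DNA. Pair density fell with distance with a slope of -0.80 ± 0.018 in GRID-seq and -1.13 ± 0.023 in Hi-C between 10 kb and 1 Mb on log10 scales (SD, n = 2 each), a difference of 0.333 (exact permutation test, two-sided, p = 0.333, the smallest it can give). With each Hi-C anchor pair counted once the difference changed sign. That setting drops the counts of read pairs between anchors, not duplicates alone, and leaves GRID-seq as it was. No background was removed from the slopes. Independent pairing would put 20.9% of GRID-seq nuclear pairs on the same chromosome, against 32.5% observed. The Hi-C pairs join called anchors, with 0 between chromosomes, so no such share can be given for them. How far these differences between the assays set the slopes was not tested. Across 145493 pairs of 100 kb bins, which are not independent, the maps had a Spearman rho of 0.753 between GRID-seq replicates, 0.654 between Hi-C replicates and a mean of 0.575 between assays (0.491 to 0.662 over 4 pairings). With each map also divided by its bin totals, the mean between assays was 0.146. The rho between replicates fell as well, to 0.234 for GRID-seq and 0.328 for Hi-C.

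**Figure D4:**
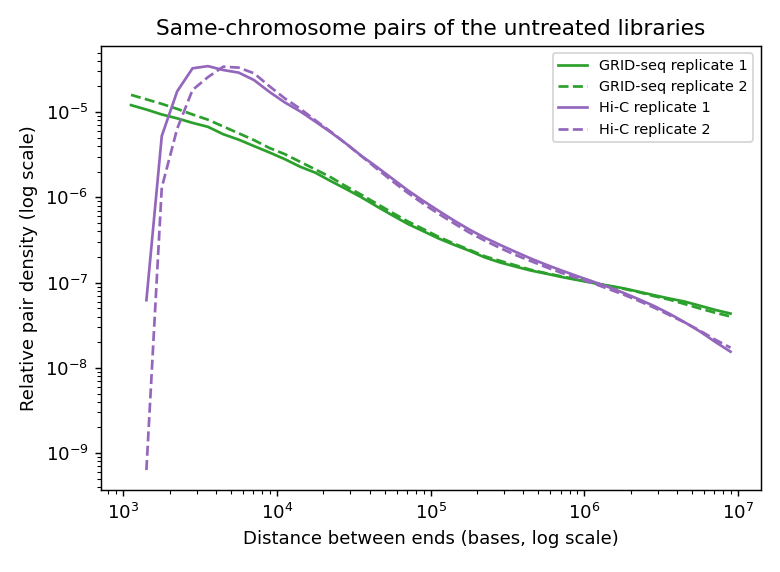
Relative pair density (vertical axis, log scale) against distance between ends in bases (horizontal axis, log scale) for same-chromosome pairs of the untreated GRID-seq and Hi-C libraries, with 1 line per library. The GRID-seq lines fall less steeply, with slopes of -0.80 against -1.13 between 10 kb and 1 Mb. No background was removed from either assay, and the Hi-C pairs are limited to called anchors.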

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

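The tests of the leaf libraries given here were chosen after the opposite directions had been seen. Pairs of a nuclear RNA end with an organelle DNA end made up 2.46% of wild type pairs. Those of an organelle RNA end with a nuclear DNA end made up 10.4%. The gene comparisons do not use these pairs, and there is no control library to set them against. Chloroplast RNA gave 8.87% of all RNA ends and 8.63% of those paired with nuclear DNA in wild type replicate 1. In replicate 2 these shares were 5.32% and 5.16%. These 2 shares are close largely because most DNA ends were nuclear. In wild type replicate 1, 2.82% of DNA ends lay on the chloroplast genome and 0.846% on the mitochondrial genome. The closeness therefore says little about how chloroplast RNA was paired.

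The first pattern is that the 2 leaf replicates moved in opposite directions against the mock of the same number. A difference of depth or library batch between the replicate numbers would move mock and DC3000 libraries alike. Across genes, replicate 1 minus replicate 2 had r = -0.131 between the groups for RNA ends (Spearman rho -0.058) and r = 0.338 for DNA ends. Same-numbered libraries did share other traits: the first-end strand share was 88.2% in mock and 90.7% in DC3000 for replicate 1, against 67.1% and 66.7% for replicate 2. The small RNA values thus argue only weakly against such a difference as the whole cause for RNA ends. An infection that failed in a single DC3000 library would not set the mock libraries apart, and their median difference over the jasmonate and coronatine list was 2.62 on the log2 scale. Such a failure alone thus does not account for the difference between the mocks. A failed infection together with another cause was not tested. Labels swapped between a mock and a DC3000 library of 1 replicate number stay open. Over 66 genes of 2 lists, 42.4% were closer to the other group in the less displaced library of replicate 1 (37.9% for replicate 2), under the stated bound of 50%. The lists disagreed, however (for replicate 1, 100% and 74.1% in the jasmonate and coronatine list, 2.56% and 100% in the photosynthesis list). Their genes are correlated (estimates of 0.611 and 0.951), and the choice to ask for both lists was made after the value was seen. The measure also compares libraries across replicate numbers and makes no allowance for a difference between the numbers. It therefore cannot decide on a swap that came together with such a difference. Across genes, among the leaf libraries, RNA ends of mock replicate 1 were closest to DC3000 replicate 2 (rho 0.894) and those of DC3000 replicate 1 to mock replicate 2 (0.890), above the 0.846 between mocks and 0.785 between DC3000 libraries, as a swap would give, but mock replicate 2 and DC3000 replicate 2 reached 0.886, and for DNA ends same-numbered libraries were closest (0.904 and 0.964); the groups were kept as the labels give them, and a response to DC3000 that differed between plants was not tested.

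The second pattern is the rise of DNA ends at heat-induced genes and at neighbours of such genes, with tests stated before their values were seen. If second ends there were RNA, they would lie on the RNA strand, and the median share was 73.8% over the 9 genes with at least 30 RNA ends (72.0% over all 10; AT5G48575 was left out after its value was seen), so RNA ligated as a second end may account for part of the rise. The neighbours AT1G74300 and AT5G52650 rose by 1.32 and 1.28, counted with 1 kb on each side. Their shares, taken in the gene bodies alone, were 54.3% and 51.4%. Ends from the adjoining heat-induced gene can enter the rise and not the share, so at these genes the strand leaves the explanation open. Reads with more than 1 second end were also tested: with single second ends the median log2 fold change was 0.666 times that over all pairs (0.89 against 1.33), between the stated bounds, so this explanation cannot be told apart from a rise in true DNA contacts. These explanations overlap, since the strand share in single second ends was lower, from 45.3% in SR45a to 61.2% in HSP90.1, and a change of the chromatin at these genes under heat stays among the open explanations.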

How the results depend on the processing

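Alternatives added after seeing the data are the read-number, short-distance, organelle, crossed-number and bin-total settings. For heat RNA ends the count of 114 stayed within 1.5 times under scaling, filters, thinning, far pairs and all ways of counting (81 to 125), and was 132 with DESeq2. It was 224 with only the 4 libraries and 624 with a replicate block (343 higher and 281 lower), and 32 to 84 when single libraries were left out. For heat DNA ends the count of 10 became 19 with own transcripts included, 31 with only the 4 libraries, 41 with a replicate block, 3 with 1 pair per read number, 0 with single second ends, and 1 to 3 without single libraries. Without single libraries the near share differed by -2.06 to 2.22 points for heat and -2.78 to 1.88 for DC3000. DC3000 RNA ends gave 0 to 3 and DC3000 DNA ends 0 to 22 without single libraries. The replicate block gave 0 calls for DC3000 and 1 for the untreated comparison. It ended the 3 calls of the heat gene lists (0 lists, with fry adjusted p = 0.250 for chaperones, 0.250 for small heat shock proteins and 0.231 for regulators). This fit estimates the block and the treatment from 4 libraries, which leaves fry little to judge the spread from. The lost calls therefore do not show a smaller effect. In the same order, the lists' median log2 fold changes in replicates 1 and 2 were 4.17 and 3.54, 4.21 and 3.71, and 1.66 and 1.59. For change of the clock list in either direction, fry gave adjusted p = 0.119 with the block and 0.131 with single second ends. Same-numbered libraries deviated together with r = 0.14 for heat and -0.13 for DC3000; with the crossed numbers as a block, DC3000 RNA ends gave 0 calls. A library left alone in its group is assumed to vary like the other groups. The wild type protein-coding share was 73.8% with single second ends. The gene body ratio was 1.19 at 2 kb, 1.17 with single second ends and 1.18 with 1 pair per read number; the pericentromere ratio was 0.256 and 0.339 at limits of 25% and 45%. The slope difference was 0.302 between 100 kb and 5 Mb. It was -0.216 with each Hi-C anchor pair counted once, which drops the counts of read pairs between anchors. The mean rho between assays was 0.348 with 50 kb bins, 0.723 with 200 kb bins, 0.299 without pericentromeric bins and 0.146 after division by bin totals. Between replicates of GRID-seq and of Hi-C, rho was 0.472 and 0.396 with 50 kb bins and 0.906 and 0.846 with 200 kb bins. Without pericentromeric bins it was 0.551 and 0.422, and after division by bin totals 0.234 and 0.328. The cause of these changes was not tested. Of 29 named heat genes for RNA ends, 26 to 28 kept their side of the threshold without single libraries; of 5 for DNA ends, 1 to 3 did, and 5 lost the call with single second ends. Among the named heat genes for RNA ends, 2 gained a call with only the 4 libraries and 6 with the replicate block. These lay in the photosynthesis or clock lists. Strand-specific counting was not run, since the gene table gives no strands, and counting identical GRID-seq pairs once changes nothing, since no pair is repeated.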

Other observations

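The wild type difference and the genes in this paragraph were picked after their values were seen. The jasmonate and coronatine list had a mean of 4.80 log2 CPM in wild type replicate 1 and 6.50 in wild type replicate 2, against 5.14 and 5.44 in the mock seedlings. Among genes outside the fixed lists, SR45a (AT1G07350), a splicing factor gene, rose by 4.03 after heat and AGO2 (AT1G31280), an Argonaute gene, by 2.50 on the log2 scale (edgeR adjusted p = 0.000878 and 0.00481). In the chaperone list GolS1 (AT2G47180), a galactinol synthase gene, rose by 3.58 (edgeR adjusted p = 0.00296).

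A hypothesis stated before its test was that RNA newly made at the locus raises the share of near pairs of RNAs that rose with heat. It was not borne out: over 111 risen genes the median near share in heat minus mock was -2.10 percentage points, below the 5th percentile of matched sets of genes with unadjusted p over 0.2 (-1.54). Without pairs under 200 bases apart the median was -0.248, within the matched range, while the median near share of the risen genes was 1.88% and 1.84% in the heat libraries and 1.31% and 1.64% in the mock libraries. These 2 summaries point in different directions, so the part played by such pairs is left open.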
